A study of Mus musculus with 3 samples.

How the data were processed

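The cells were a mouse leukaemia line driven by NUP98-HOXD13, a fusion of the nucleoporin NUP98 with the homeobox protein HOXD13. The fusion carried biotin, and BioChIP-seq recovers the DNA crosslinked to such a protein on streptavidin beads in place of an antibody. Cells received DMSO or 2 µM VTP50469, an inhibitor of the contact between menin and MLL, and the libraries were sampled at 96 h, per the labels' protocols. Chromatin was sheared mostly to 100 to 700 bp, and was sequenced with paired 37 bp reads. The series held 3 samples: a DMSO input, a DMSO pull-down and a VTP50469 pull-down, with 1 library in each group. The input was not analysed here as a file of its own.

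The authors deposited 1 peak list for each pull-down, so peaks were called per library and not on pooled samples. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.5a, Picard 2.9.4, SAMtools 1.95, MACS2 and bedtools, and the mm10 build. The role of each tool, its settings, the calling threshold and the control used are not given in the sources used here. In the authors' lists each peak has a fold enrichment, which is a ratio of the library to a background, and a −log10 p-value and a −log10 q-value. The deposited score equalled the whole part of 10 times the −log10 q in 655 of 655 DMSO rows and 439 of 439 VTP50469 rows, and was not used further. The lowest −log10 q was 2.10 in the DMSO list and 2.02 in the VTP50469 list, and no interval occurred more than 1 time in either list. These values are the authors' own and served to describe, rank and filter peaks within their list. The lists give no read totals, so the depth of each library was not read from them directly.

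From these lists, peaks on chromosomes 1 to 19, X and Y were kept, and peaks on other sequences are reported apart. A peak was shared when at least 1 bp overlapped a peak of the other list. Overlaps were set beside 1000 random placements of the other list within its chromosomes. Shares have exact Clopper-Pearson 95% intervals. The intervals cover counting error only, because nearby peaks are not independent and a single library carries no replicate error. Peaks whose summits lay within 50 kb of the next were chained, and chains of at least 3 peaks were counted as clusters. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

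Gene positions came from a RefSeq table of GRCm38.p6, whose primary assembly is that of mm10, with 21887 protein-coding genes on these chromosomes. The table gave gene spans without strand, exons or transcript starts, so a summit inside a gene span could lie in an exon, an intron or a UTR. The planned share of peaks at promoters was replaced by the share of summits within 2 kb of either end of a gene span. The planned count of sequence motifs at summits was not run, since no genome sequence was used here. There were 13 gene lists, written before the data were examined, with 249 genes in all, and 248 of them were found in the table. A gene had a peak when a summit lay in its span or within 10 kb. Each list was set beside 10000 random lists of equal size, matched on gene length in 10 bins, which describes these libraries and is not a test. The gene assignment was tested on simulated peaks and found 300 of 300 planted genes.

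Named genes followed a rule set before the data were examined. They were up to 4 members of each list by −log10 q, and the nearest gene of the 10 strongest peaks among shared peaks and those of either list alone. To these were added the genes of the 5 clusters with the most DMSO peaks, and Meis1, Hoxa9, Hoxa10, Pbx3, Cdk6 and Mef2c whatever their values. Alternatives covered the strength threshold, the overlap rule, the length of the lists, the distance to genes and the cluster gap.

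For the closing observations only, fragment counts at summits were rebuilt from the authors' fold and p-value. The rebuilding assumed a Poisson model with a pseudocount of 1 and whole fragments scaled to the control. The listed −log10 p was matched within 0.001 at 368 of 368 DMSO peaks and 234 of 234 VTP50469 peaks that lay at the common background. Counts were obtained for 608 of 613 DMSO and 395 of 400 VTP50469 peaks on the chromosomes. On 600 simulated peaks per setting, at least 95% of counts were right and 0% were wrong, the remainder being left unsolved. The simulated peaks were drawn from the same model at low backgrounds, so accuracy at high-coverage summits was not tested. Summits within 200 bp were compared by exact binomial tests with Benjamini-Hochberg adjustment, which compare 2 libraries and not the treatments.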

Results

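Peaks of the biotinylated NUP98-HOXD13 fusion were compared between leukaemia cells given DMSO and cells given 2 µM VTP50469 for 96 h. The comparison asks where the fusion is found on chromatin with and without the menin-MLL inhibitor. There was 1 library per treatment and no replicate, so no test across samples was possible, and every difference below is between 2 libraries. The DMSO list had 613 peaks on the chromosomes and the VTP50469 list had 400. They covered 313 kb and 204 kb of the mm10 genome, with median peak widths of 350 and 335 bp. The median fold enrichment over background, as the authors' peak caller gave it, was 7.64 in the DMSO list and 7.33 in the VTP50469 list.

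Peaks at the Hoxa, Hoxb and Hoxc clusters, which encode homeobox transcription factors of body patterning and blood progenitors, were found in both libraries. Leukaemia-associated genes such as Meis1, Mef2c and Eya1 had peaks in the DMSO list alone, and Pbx3, Runx2 and Zcchc7 had fewer peaks with VTP50469. Of the 613 DMSO peaks, 305 overlapped a VTP50469 peak, or 49.8% (45.7 to 53.8%). Of the 400 VTP50469 peaks, 311 overlapped a DMSO peak, or 77.8% (73.4 to 81.7%). That left 308 peaks in the DMSO list alone and 89 in the VTP50469 list alone. Random placement gave a mean of 0.085 overlapping DMSO peaks and at most 2 in 1000 placements. With both lists held to their 400 strongest peaks the shares were 60.3% and 62.0%, which are close by construction at equal length, so the asymmetry above goes with the difference in list length.

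Overlap rose with peak strength, taken as −log10 q, in both lists. In the DMSO list, 42 of 154 peaks in the weakest of 4 equal bins by −log10 q overlapped a VTP50469 peak, or 27.3% (20.4 to 35%). The middle bins gave 35.3% (27.7 to 43.4%) and 49.7% (41.5 to 57.9%), and in the strongest bin 133 of 153 peaks overlapped, or 86.9% (80.5 to 91.8%). In the VTP50469 list the bins gave 55%, 70.0%, 86.0% and 100.0%, and 100 of 100 peaks of its strongest bin lay on a DMSO peak (96.4 to 100.0%). Peaks found in the DMSO list alone had a median fold of 6.89, against 9.25 for the shared peaks of that list. In the VTP50469 list the medians were 6.05 for the peaks of that list alone and 8.13 for the shared ones.

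**Figure D1:**
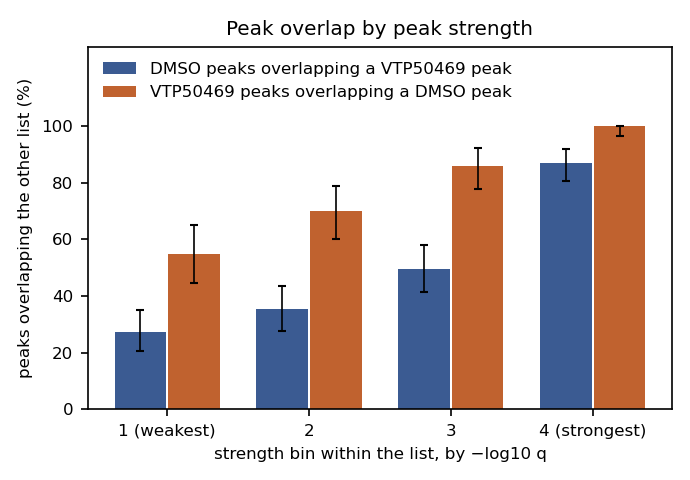
Percent of peaks that overlap the other list (vertical axis) by strength bin, 4 equal bins of −log10 q within each list (horizontal axis), with DMSO peaks in blue and VTP50469 peaks in orange; error bars are exact 95% binomial intervals. The blue bars run from 27.3% to 86.9% and the orange bars from 55% to 100.0%.

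The 10 strongest shared peaks of the DMSO list lay in or near Strbp, Trdmt1, Sos2, Hoxa3, Pbx3, Hibadh and the overlapping genes Runx2 and Supt3, and in 3 high-coverage intervals. The peak in Strbp, which encodes an RNA-binding protein, had the highest fold on the chromosomes, 61.4, at chromosome 2, 37683803 to 37685120. Trdmt1, a tRNA methyltransferase gene, had a peak of fold 39.9 at chromosome 2, 13538285 to 13538780. The peak nearest to Sos2 had a fold of 31.6 and its summit lay 3883 bp outside the gene span. The peak nearest to Hibadh had a fold of 28.0 and lay 33485 bp outside that gene. The strongest Hoxa peak, at chromosome 6, 52213210 to 52213636, had a fold of 28.8 and its summit lay 386 bp outside the Hoxa3 span. That span also covers Hoxa5 and Hoxa6, and the summit lay 2170 bp from Hoxa7 and 4781 bp from Hoxa6. The 3 high-coverage intervals, nearest to Gm2244 and Alkbh8, had folds of 1.51, 2.51 and 1.67 and lay 115435 bp or more from any protein-coding gene.

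Among the 10 strongest peaks of the DMSO list alone, 3 lay in Zcchc7, which encodes a zinc finger protein of RNA surveillance, and 1 each in Umad1, Pbx3, Dennd1a, Rab38, Tsc22d2 and Pcdh7. The tenth lay 141 bp outside Cp, the ceruloplasmin gene. The Umad1 peak, at chromosome 6, 8333913 to 8334573, had a fold of 20.8, the highest of the peaks in the DMSO list alone. The Pbx3 peak, at chromosome 2, 34244727 to 34245143, had a fold of 9.28, and the peak beside Cp a fold of 14.1. The 3 Zcchc7 peaks had folds of 14.7, 13.8 and 13.8. The folds in Dennd1a, Tsc22d2, Rab38 and Pcdh7 were 13.9, 13.2, 11.8 and 11.2.

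The 10 strongest peaks of the VTP50469 list alone had folds from 6.01 to 9.58. The highest fold was that of a peak in Lyst, a lysosomal trafficking gene, at chromosome 13, 13614173 to 13614470, and a peak 14996 bp from Gm17778 had the same value. Peaks in Map4k5, Oxr1, 4930467E23Rik and Cdh12 had folds of 8.05, 8.00, 6.01 and 8.45. The peak with the highest −log10 q, 16.2, lay 3768 bp from the olfactory receptor gene Olfr172 and had a fold of 9.03. The other 3 lay 113690 bp from Cited2, 146275 bp from F13a1 and 1475909 bp from Cdh9, with folds of 8.45, 8.14 and 9.09.

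Members of the Hox gene lists had peaks in both libraries. In the Hoxa cluster 6 of 11 genes had a peak in the DMSO list and 6 in the VTP50469 list, and the same 6 genes had one in both. The numbers were 4 of 10 Hoxb genes and 4 of 9 Hoxc genes in each list, again the same genes, and 0 of 9 Hoxd genes in either. None of the random lists (0.00%) held as many genes with a peak as the Hoxa, Hoxb or Hoxc lists, though neighbouring Hox genes share peaks and random genes do not. The Hoxa genes rested on 5 peaks in each list, the Hoxb genes on 2 in each, and the Hoxc genes on 4 DMSO and 3 VTP50469 peaks. Of the 5 Hoxa peaks in the DMSO list 4 were shared, and 1 of these (52216698 to 52217582) overlapped 2 VTP50469 peaks. Hoxa7 and Hoxa9 lay among the 5 Hoxa peaks, and the peak just inside one end of the Hoxa9 span (chromosome 6, 52223112 to 52223411, fold 12.0) was in the DMSO list alone. A second peak inside Hoxa9 was shared. The nearest peaks to Hoxa10, a neighbouring regulator of blood progenitors, lay 4838 bp away in the DMSO list and 4844 bp away in the VTP50469 list. At the Hoxb cluster a peak inside Hoxb8 (chromosome 11, 96281566 to 96282271) had a DMSO fold of 26.1, and the overlapping VTP50469 peak had a fold of 24.2 in its own list. The second, 461 bp from Hoxb6 in the VTP50469 list, was shared too. At the Hoxc cluster the peaks inside Hoxc5 (chromosome 15, 103014405 to 103014865) and Hoxc4 (103032644 to 103033120), and the one beside Hoxc6, were shared. A weaker Hoxc5 peak of fold 7.19 was in the DMSO list alone. With a flank of 2 kb in place of 10 kb, 3 Hoxa and 2 Hoxb genes had a peak in each list, and with 50 kb 10 Hoxa, 7 Hoxb and 7 Hoxc genes did.

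Of 35 genes of leukaemia and self-renewal, 9 had a peak in the DMSO list and 3 in the VTP50469 list. Random lists held a mean of 1.49 and 1.13 such genes, and 0.00% of them reached 9 with the DMSO peaks and 9.95% reached 3 with the VTP50469 peaks. The 3 genes with a peak in both were Pbx3, Runx2 and Cdk6. Pbx3, which encodes a partner of HOX and MEIS proteins, had 7 peaks with DMSO and 2 with VTP50469. Runx2, a runt-domain transcription factor gene, had 3 and 1, and Cdk6, a cell-cycle kinase gene, had 1 and 2, both of the latter overlapping the single DMSO interval. Eya1, a transcriptional coactivator gene, had 3 DMSO peaks, the strongest with a fold of 11 at chromosome 1, 14306024 to 14306378, and no VTP50469 peak. Meis1, the HOX cofactor gene, had 1 DMSO peak of fold 7.05 whose summit lay 4211 bp outside its span, and the nearest VTP50469 peak was 2701 kb away. Mef2c, a myeloid and lymphoid transcription factor gene, had 1 DMSO peak of fold 8.22 inside its span, and the nearest VTP50469 peak was 3097 kb away. The other 3 genes, Bcl11a, Myb and Mecom, named here after their values were seen, each had 1 DMSO peak with folds of 9.29, 6.89 and 5.50, and no VTP50469 peak. Of all 325 protein-coding genes with a DMSO peak, 187 also had a VTP50469 peak, and whether the leukaemia list departed from that share was not tested. The single peaks of Meis1, Mef2c, Bcl11a, Myb and Mecom all lay below the strongest of the 4 bins of DMSO peaks, where 49.7% or fewer were shared.

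**Figure D2:**
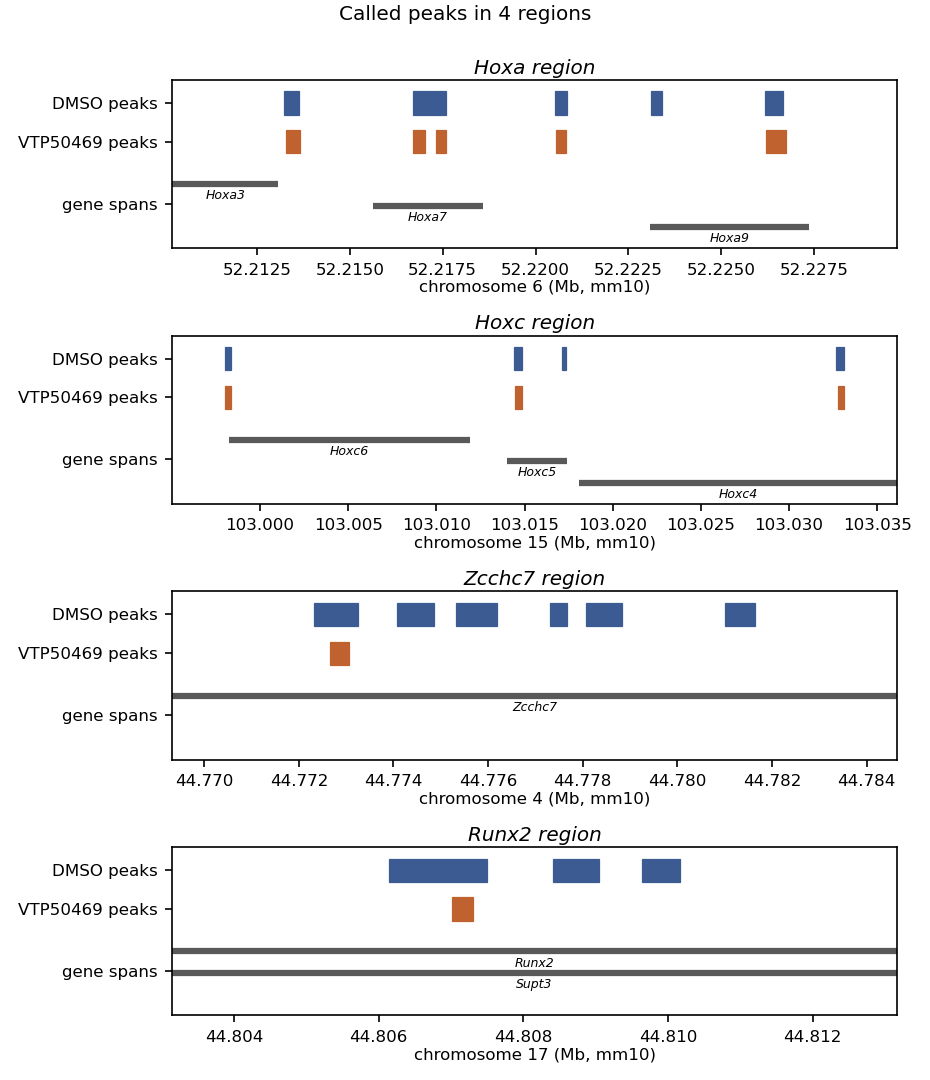
Called peaks along 4 regions (horizontal axes, position in Mb on mm10), with DMSO peaks in blue, VTP50469 peaks in orange and protein-coding gene spans in grey, all to scale. The Hoxa region held 5 peaks in each list and the Hoxc region 4 and 3, against 6 and 1 in Zcchc7 and 3 and 1 in Runx2. In the Hoxa region 4 of the 5 DMSO peaks were shared, 1 of them with 2 VTP50469 peaks.

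In the other gene lists few or no members had a peak. Of 20 genes of MLL and menin complexes, Kat6b, a histone acetyltransferase gene, had a peak, in both lists, at chromosome 14, 21505135 to 21505486. A second Kat6b peak, at 21507245 to 21507507 with a fold of 4.50, was in the VTP50469 list alone. With the DMSO peaks 33.5% of random lists held as many genes with a peak. None of the members of the other lists had a peak in either library. These were 28 genes of myeloid differentiation, 18 lymphoid markers, 14 erythroid and megakaryocyte genes, 26 nucleoporin genes, 29 genes of other tissues, 9 genes of biotin-dependent carboxylases and related proteins, and 31 ribosomal protein genes. Random lists of those sizes held means of 0.066 to 0.428 genes with a DMSO peak, so a count of 0 was no departure. Over all lists, 24 genes had a peak in the DMSO list and 18 in the VTP50469 list.

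There were 39 clusters of 3 or more DMSO peaks, holding 148 of them, and 14 such clusters of VTP50469 peaks, holding 47. The cluster with most DMSO peaks lay in 9930021J03Rik (chromosome 19, 29733519 to 29752495), with 8 DMSO and 2 VTP50469 peaks. Zcchc7 (chromosome 4, 44772325 to 44781642) held 6 and 1, and Tut4, a terminal uridylyltransferase gene (chromosome 4, 108537579 to 108544643), held 6 and 1. Mid1, a ubiquitin ligase gene (chromosome X, 169989468 to 170005544), held 6 and 4. A further cluster of 6 and 5 peaks, outside gene spans on chromosome 9 from 3001180 to 3038076, held 2 of the high-coverage intervals named above.

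Peaks of the DMSO list alone lay inside protein-coding genes more often than shared peaks. Their summits fell in a gene span in 215 of 308 cases, or 69.8% (64.3 to 74.9%), against 159 of 305 shared DMSO peaks, or 52.1% (46.4 to 57.9%), and these intervals did not overlap. Peaks of the VTP50469 list alone did so in 39 of 89 cases, or 43.8% (33.3 to 54.7%), and random sites on the same chromosomes in a mean of 40.1%. Taking the strongest peak of each chain, which was chosen after seeing the data, gave 64.4% (58.2 to 70.3%) for the DMSO list alone and 51.0% (44.6 to 57.4%) for shared peaks. Few summits lay near gene ends: 53 of 613 DMSO peaks were within 2 kb of one, or 8.65% (6.54 to 11.2%), and 36 of 400 VTP50469 peaks, or 9.0% (6.38 to 12.2%), against a mean of 6.22% of random sites.

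**Figure D3:**
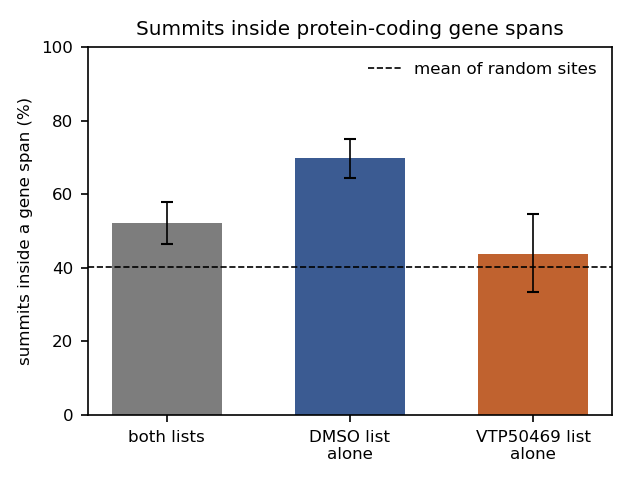
Percent of peak summits inside a protein-coding gene span (vertical axis) for DMSO peaks shared with the VTP50469 list (grey), peaks of the DMSO list alone (blue) and peaks of the VTP50469 list alone (orange); error bars are exact 95% binomial intervals and the dashed line is the mean of random sites, 40.1%. The values are 52.1%, 69.8% and 43.8%.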

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

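The test of local background below was chosen only after the result was seen. Outside chromosomes 1 to 19, X and Y, 42 DMSO peaks and 39 VTP50469 peaks lay on unplaced or patch sequences and on the mitochondrial genome, 3 of each on the latter. They stood out because they are signal outside the main comparison. Of the 42 DMSO peaks, 37 overlapped a VTP50469 peak, or 88.1% (74.4 to 96.0%). Their median fold in the authors' DMSO list was 2.52, against 7.64 on the chromosomes.

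A candidate explanation for these peaks is coverage that the control shares, from repeats or from DNA present in many copies. The local background rebuilt at these summits was a median of 13.7 times the genome background in the DMSO list, above the range of the simulated peaks. At 22 summits matched between the lists the median ratio of VTP50469 to DMSO fragments, scaled for depth, was 0.995. The ratios ran from 0.564 to 1.76, and by adjusted exact binomial tests 2 summits were lower and 2 higher with VTP50469. The raised background goes with that explanation, but the fold is already a ratio to a background. The median ratio would also follow from binding that did not differ between the libraries, so neither median decides. The summits that differed were not accounted for. Binding of the fusion at some of these sequences stays open. No biological explanation was tested for them.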

How the results depend on the processing

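The settings for gene ends, gene spans, local background and fragment counts were chosen after seeing the data, and all others before. Of 156 alternative values 124 stayed close to the main value and 32 moved, and none turned a direction when taken singly. With strength taken as fold, however, the weakest DMSO bin was shared more often than the next bin. Peak counts stayed within 1.5 times the main value at −log10 q of at least 2 or 5, at a fold of at least 5 and over all sequences. At −log10 q of at least 10 there were 308 DMSO and 194 VTP50469 peaks. The shared shares were then 54.2% and 87.1%, and why they moved was not tested. With only the queried list held to −log10 q of at least 5 the shares were 55% and 83.6%. At equal list length they were 60.3% and 62.0%. Extending peaks by 1 kb gave 54.0% of DMSO peaks. Reciprocal overlap of at least 50 percent gave 71.0% of VTP50469 peaks, and summits within 200 bp gave 72.8%. By fold in place of −log10 q, 36.4% of the weakest DMSO bin and 31.4% of the next were shared, so overlap did not rise between them. The stronger DMSO bins gave 49.0% and 82.4%, and the cause was not tested. Gene ends within 1 kb gave 4.73% of DMSO and 4.25% of VTP50469 peaks, and within 5 kb 17.3% and 19%, by construction. With a flank of 50 kb, 29 listed genes had a VTP50469 peak. At −log10 q of at least 5, 75.9% of peaks in the DMSO list alone lay in gene spans, and the cause was not tested. At a rebuilt local background under 3 the gap to shared peaks narrowed. The shares were then 70.3% (64.6 to 75.5%) for the DMSO list alone and 56.4% (50.2 to 62.5%) for shared peaks.

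No paired analysis was possible because each treatment had 1 library. Promoter shares and summit sequences were not run, as no transcript starts or genome sequence were used here. Read totals are not in the lists, so the precision of each peak rests on the authors' calls, and single weak peaks are the least certain.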

Other observations

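All tests in this part were chosen only after the result was seen, and the comparison of fragments was devised after the lists had been examined. The non-coding genes and Nr4a2 were named after their values were seen.

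Peaks also lay at non-coding genes. Summits fell in or within 2 kb of 45 long non-coding RNA genes in the DMSO list and 39 in the VTP50469 list. The strongest shared ones were at Hoxaas3 and Mira, beside Hoxa3 and Hoxa7, at Hoxb5os in the Hoxb cluster, and at Dleu2. The DMSO summit in Dleu2, at position 61646223 of chromosome 14, had a fold of 18.2. The microRNA gene with a peak was Mir615, inside the Hoxc cluster, whose summit lay 288 bp away in the DMSO list and 248 bp away in the VTP50469 list. Gm46952, which overlaps Umad1, held a peak of the DMSO list alone with a fold of 20.8.

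Rebuilt fragment counts allowed the heights of matched summits to be compared between the 2 libraries. The comparison assumed that both lists used the same control, which no source states. Of 286 matched summits 172 lay at the genome background in both lists and say little about this. At the other 114 the local background differed by at most 5% at 78, and at the 15 with a DMSO background of 5 or more at 11. On that assumption the VTP50469 library had a depth 5.50% lower than the DMSO library. After scaling for depth, the median ratio of VTP50469 to DMSO fragments was 0.90 (interquartile range 0.753 to 1.04), and 194 of 286 summits lay below 1. By exact binomial tests with Benjamini-Hochberg adjustment 28 summits were lower and 0 higher with VTP50469, and without adjustment 57 were lower and 4 higher. Centred on the median ratio the counts were 13 lower and 3 higher. The lowest ratio was at Runx2 and Supt3 on chromosome 17 (189 and 50 fragments, ratio 0.280, 95% interval 0.201 to 0.384). Zcchc7 had 0.322 (0.237 to 0.432), Nr4a2 0.464 (0.344 to 0.621) and the strongest Pbx3 peak 0.558 (0.432 to 0.716). The 4 matched Hoxa summits had ratios from 0.684 to 0.817 with a median of 0.762, the 2 Hoxb summits 0.916 and 0.952, and the 3 Hoxc summits 0.668, 0.967 and 1.00. For 2 Hoxa summits and the Hoxc4 summit the unadjusted exact p was 0.019, 0.028 and 0.016. The lowest adjusted p of these 9 summits was 0.11. The median was 0.812 among the strongest of 4 bins of DMSO peaks and 0.958 among the strongest of 4 bins of VTP50469 peaks, so part of the drop at strong DMSO peaks goes with choosing them by DMSO height.

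At peaks of the DMSO list alone, the height that could have stayed uncalled with VTP50469 bounds the ratio. Even at that height 189 of the 308 were lower with VTP50469, and 117 after centring on the median ratio. The Hoxa9 and Hoxc5 peaks of the DMSO list alone were among the 189. In the other direction, 26 of the 89 peaks of the VTP50469 list alone were lower with DMSO. These peaks were picked for being tall in one list, and a peak can also go uncalled for being narrow, which can raise the counts. Taking the tallest uncalled height can lower them, and the bound takes the local background to be equal. The counts are therefore neither upper nor lower limits. They cover counting error between 2 libraries.

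The pattern of fewer peaks with VTP50469 was weighed against depth, pull-down strength and treatment. Thinning the DMSO fragments to the VTP50469 depth left 607 of 608 DMSO peaks above the height threshold (603 to 608 over 1000 draws). With redrawn counts the median was 593 and the lowest 582. Given a shared control, both versions argue against depth. An equally weaker pull-down at every site would let neighbours share their outcome no more than peaks of like strength, if neighbours were alike in nothing else. Of 160 neighbouring DMSO pairs within 50 kb, 93 had the same outcome, against a mean of 78.7 in permutations within 4 strength bins and 78.7 within 20 strength bins (one-sided permutation p = 0.013 in each of the 2 versions run). Neighbours thus shared their outcome more often than peaks of like −log10 q. The permutations did not match local background, which neighbours can also share, so they cannot decide against an even loss. A loss at particular loci with VTP50469 is a hypothesis that stays open, since with 1 library per treatment an effect of VTP50469 on binding cannot be told apart from variation between libraries or cultures.

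Of 29 VTP50469 peaks on chromosome 15, 14 were in that list alone, against 7.74 for peaks of like strength, the largest excess among chromosomes (one-sided permutation p = 0.11, so chance was not excluded). An extra copy of chromosome 15 in the VTP50469 cells, 3 in place of 2, could give such a gathering. In all cells it would raise coverage 1.5 times. The median fragment ratio at the 14 matched summits there was 1.12 times that of the other chromosomes (95% bootstrap interval 0.829 to 1.25), which argues against a gain in all cells, if binding there changed as elsewhere. A gain in part of the cells cannot be told apart from none, as the interval includes 1.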
